A study of Heliophilum fasciatum with 15 samples.

How the data were processed

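RNA was sequenced from cultures of Heliophilum fasciatum, an anaerobic phototrophic bacterium of the heliobacteria, which are anoxygenic phototrophs. Cultures grew in a defined medium with 20 mM pyruvate and 20 mM ammonium chloride, and sulfate, thiosulfate or methionine was the added sulfur source. Sulfate and thiosulfate were added to 5 µM or 1 mM, and methionine to 1 mM. The trace element solution of the medium contained nickel and vanadyl sulfates, per the labels' protocols, so a small amount of sulfate was present in every culture. Cells from 5 ml of culture were stabilised in RNAprotect reagent, RNA was isolated with the RNeasy kit, and libraries were made with Illumina's kit for stranded total RNA, per the labels' protocols. The kit was used at reduced reagent volume.

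The authors' file is a table of whole-number read counts per gene for 15 libraries, not normalized, which the authors deposited for the whole series. Per the file headers, reads were counted with featureCounts 2.0.8 on features of type gene of annotation ASM434139, on the reverse strand (strand option 2), with duplicate reads ignored. The header's command has no option for multi-mapping reads, for reads overlapping several genes, or for counting read pairs in place of reads. Genes that share reads with a near-identical copy may therefore be under-counted, depending on how the aligner marked such reads, and reads in the overlap of same-strand genes were dropped. Leaving out duplicates lowers the most abundant genes most, and the highest density in any library was 283.5 reads per base. Per the submitters' processing notes, Trimmomatic 0.38, Bowtie2 2.5.1, SAMtools 1.17, Picard 3.0.0 and Subread were used; their settings are not given in the sources used here.

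The table lists 2957 genes on 73 contigs, of which 70 had 0 reads in all libraries. No line was a total or an unassigned class, and each of the 15 columns matched the library name of 1 sample. Contigs are written here by the number in their name, and coordinates are those of the file. The file gives locus identifiers and does not pair them with gene names, and no gene name table or genome was used here, so lists of sulfur, nitrogenase and other genes fixed in advance could not be filled and were not tested. Genes for ribosomal and transfer RNA could not be set apart for the same reason.

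After the library name, the column headers carry a number, 364, 367 or 368. It was read here as a sequencing run tag, and runs are counted in the order of these numbers. All libraries of 5 µM sulfate and of 1 mM thiosulfate, 1 mM sulfate A and 5 µM thiosulfate C came from the first run. The second run held 1 mM sulfate B and C, 5 µM thiosulfate A and B, and methionine B and C, and the third held methionine A alone.

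Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (limma 3.58.1). Genes with low counts were removed with filterByExpr, which left 2708 genes and removed 249, and library sizes were scaled by TMM, with factors from 0.8393 to 1.125. A model of 5 group means was fitted to all 15 libraries with robust quasi-likelihood dispersions and 10 residual degrees of freedom, so every comparison shares 1 estimate of the spread. Replicates did not spread alike: r between them was 0.989 to 0.992 in 1 mM sulfate and 0.939 to 0.989 in 5 µM sulfate. A shared estimate can thus be too wide for the steadier groups and too narrow for the others. Each contrast was tested 2-sided with glmQLFTest, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. An interaction contrast tested whether the concentration effect differed between thiosulfate and sulfate. Standard errors were taken as the size of the log2 fold change divided by the square root of F, and CPM are counts scaled to library size and TMM factor, given as mean ± SD of 3 libraries.

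Because genes had no names, reads were also summed over gene clusters, meaning neighbouring genes on 1 strand with gaps of at most 100 bp and at least 3 genes. There were 322 such clusters with 1581 genes, the largest of 31 genes, and they were tested with the same model. A cluster defined this way is a guess at a transcription unit and was not checked against transcript ends.

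The comparisons, the gene-level test, the rule for named genes and the alternatives were chosen before the data were examined, except those listed next. Chosen after the file was seen were the gene clusters and their alternatives, a sequencing run term and fits within 1 run. Also chosen then were fits without a pair of libraries taken to lie apart from their groups. Further fits took each of that pair as a group of its own. Genes named in the text were those with an adjusted p under 0.05, a mean count of at least 50 over the 6 libraries and no overlap of log CPM between the groups. Of these, the 2 with the highest and the 2 with the lowest log2 fold change per comparison are given by identifier; the planned omission of genes with uninformative products could not be applied. Clusters named are among the 4 highest and 4 lowest by log2 fold change of those called, and other features are said to be chosen after their values were seen.

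Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, removal of the 10 genes with most reads, a 2-fold limit, a fit to only the libraries compared, the replicate letter as a block, and each library left out in turn. Cluster gaps of 50 and 200 bp were tried as well.

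The labels give each replicate letter a batch number, so letters pair the libraries across groups, and a fit with this replicate block was one of the alternatives. As a check, deviations from the group means were correlated between libraries. For the 30 pairs with the same letter r ran from -0.452 to 0.605 with a median of -0.02, and 9 were over 0.1. For the 60 other pairs between groups r ran from -0.546 to 0.432 with a median of -0.02, and 19 were over 0.1.

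The procedure was tested on simulated data drawn with the fitted dispersions and library sizes. Apart from the changes put in, each gene had the same mean in every group, its average over all 15 libraries. In each comparison 100 genes were changed 2-fold and 100 changed 4-fold. Over the 6 comparisons between groups, 40 to 58 of the 2-fold changes and 87 to 95 of the 4-fold changes were recovered, with 4 to 11 false calls. Of 30 clusters changed 2-fold, 12 to 21 were recovered. In the gene simulations, genes varied independently, no library lay apart from its group, and both sets changed at once. Recovery in the real comparisons may therefore be lower.

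Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Replicate libraries of a group were compared before averaging. Chi-square per degree of freedom between them ran from 44.11 to 638.2, so no pair agreed within sampling noise as repeated counts of the same library would. This does not show that the cultures were separate.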

Results

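RNA-seq read counts were compared between Heliophilum fasciatum cultures given 5 different sulfur supplies, with 3 libraries (A, B and C) per group. Sulfate must be reduced to sulfide before its sulfur enters cysteine, thiosulfate carries sulfur that is already partly reduced, and methionine is an organic source. The libraries held 7652876 to 13344855 counted reads. Totals of replicates A, B and C were 11062729, 10741643 and 10484687 for 5 µM sulfate, 13344855, 11887499 and 8946471 for 1 mM sulfate, and 8164259, 8902889 and 12371435 for 5 µM thiosulfate. They were 7652876, 12016471 and 11317577 for 1 mM thiosulfate and 8702778, 7758595 and 9866088 for 1 mM methionine. Between 106 and 177 of the 2957 genes had 0 reads in a library, and the 10 most abundant genes took 7.93% to 12.99% of the reads.

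The first principal component held 45.4% of the variance in log2 CPM and the second 20.5%. Replicates correlated at r = 0.939 to 0.992 across genes. In 5 µM sulfate, libraries A and C correlated at 0.989, whereas B correlated at 0.940 with A and 0.939 with C and lay closest to 5 µM thiosulfate A, at 0.978. Library C of 5 µM thiosulfate lay closest to 1 mM sulfate B, at 0.986, and had a mean r of 0.955 to its own group, and library B of that group, with a mean r of 0.958, lay closest to methionine B, at 0.984. In the column headers, the libraries of the first run carry sample numbers 188 to 195 in column order, except that 5 µM sulfate B has 192 and 5 µM thiosulfate C has 189, each the number that column order gives the other. All libraries enter the comparisons as labelled.

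**Figure D1:**
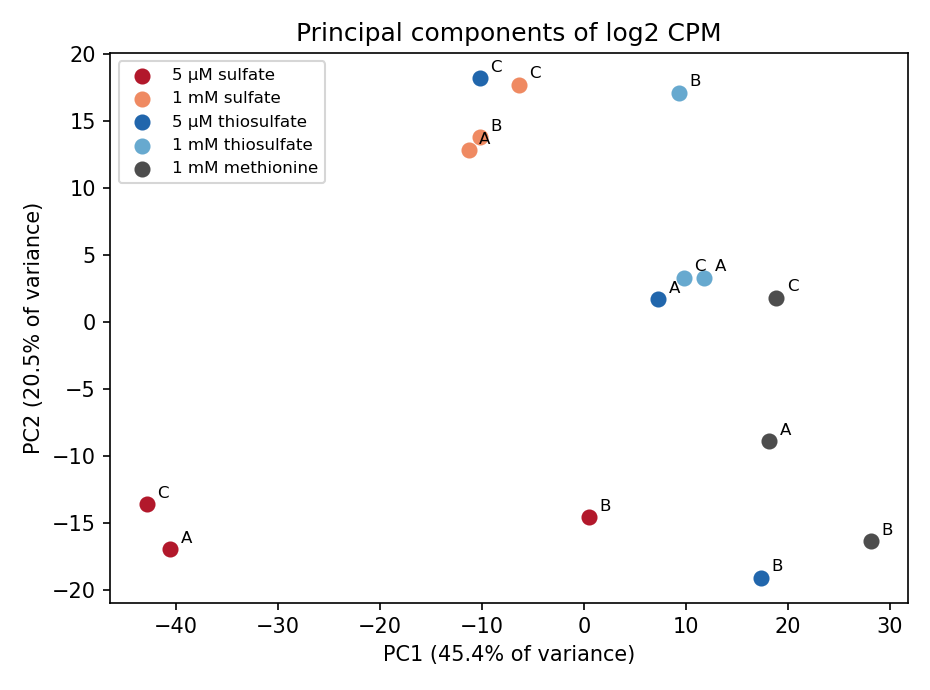
Principal components of log2 CPM for 15 libraries, coloured by group and marked with the replicate letter; axes give the percentage of variance (PC1 45.4%, PC2 20.5%). In 5 µM sulfate, libraries A and C lie together and B lies apart from them.

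The first question was how the transcriptome differed between scarce and ample sulfate. At 5 µM sulfate, a cluster of 5 genes on contig 7 (110454 to 116475) stood at 17580 ± 2867 CPM against 4221 ± 824.3 at 1 mM (SD, n = 3), a log2 fold change of 2.06 ± 0.50 (SE). A cluster of 3 genes on contig 19 (24552 to 26905) rose by 1.80 ± 0.32, and a cluster of 4 genes on contig 2 (942 to 5088) by 1.79 ± 0.39. In the opposite direction, adjacent clusters on contig 15 were lower at 5 µM, by -2.45 ± 0.38 for 3 genes at 59156 to 62347 and by -2.81 ± 0.45 for 4 genes at 62507 to 66171. The latter stood at 216.7 ± 88.12 CPM at 5 µM and 1524 ± 199.7 CPM at 1 mM. A cluster of 5 genes on contig 8 (41194 to 45852) fell from 15520 ± 1794 to 5467 ± 1259 CPM, a log2 fold change of -1.51 ± 0.21. In each of these 6 clusters, all 3 libraries of one group lay above all 3 of the other. Adjusted p-values were 0.008508, 0.001178, 0.005456, 0.0007387, 0.0007387 and 0.000331 in the order given (edgeR's quasi-likelihood test, Benjamini-Hochberg). A cluster of 3 genes on contig 5 (91148 to 92754), also among the 4 highest, rose by 1.74 ± 0.61. Its call was lost under 8 of 10 alternatives. A cluster on contig 12 (39636 to 42443), among the 4 lowest, stood at -1.56 ± 0.37 and kept its call under all 10.

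Among the single genes that met the naming rule, EDD73_RS00690 on contig 1 (140061 to 141308) rose most, to 2631 ± 1883 CPM at 5 µM from 245.9 ± 20.31 CPM, a log2 fold change of 3.42 ± 0.50 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.001155). Its neighbour EDD73_RS14750 (139667 to 139822) rose by 3.18 ± 0.63 (edgeR, adjusted p = 0.00458). Within the contig 15 cluster, EDD73_RS09150 (63383 to 64084) was lower at 5 µM, with a log2 fold change of -3.02 ± 0.55 (edgeR, adjusted p = 0.003028). The lowest value, -4.08 ± 1.1 for EDD73_RS13520 on contig 37 (18143 to 18694; edgeR, adjusted p = 0.01936), rested on 1 mM sulfate B, without which it was -1.41 (adjusted p = 0.197). Its adjusted p was also 0.0783 without 5 µM sulfate A and 0.0507 without 5 µM sulfate C, 0.06514 with only the libraries compared and 0.07609 with a sequencing run term, and ran from 0.0176 to 0.197 over its alternatives.

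In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 649 of 2708 genes, 291 higher and 358 lower at 5 µM, of which 345 changed at least 2-fold. Of 322 clusters, 28 were higher and 63 lower. Without 5 µM sulfate B, 979 genes were called. Leaving out 5 µM sulfate A or C gave 285 or 369, and leaving out 1 mM sulfate A, B or C gave 383, 343 or 274. Clusters called fell to 56 without 5 µM sulfate A. With a sequencing run term, 433 genes and 69 clusters were called, and EDD73_RS14750 was no longer called (adjusted p = 0.05635, over alternatives 1.314e-06 to 0.05635). The cluster of 6 genes on contig 7 at 130956 to 136719, described below for the other comparisons, stood at 1575 ± 629.5 CPM at 5 µM and 590.1 ± 324.7 CPM at 1 mM sulfate, and its log2 fold change of 1.42 missed the threshold (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.1544). With a sequencing run term this fold change was 0.70 (edgeR, adjusted p = 0.6369). Within the first run, where 3 libraries of 5 µM faced only 1 of 1 mM, it was 1.26.

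For thiosulfate, the same change in concentration gave 1 called cluster, a group of 6 genes on contig 7 (130956 to 136719). It stood at 145.3 ± 123.7 CPM at 5 µM and 7.082 ± 2.669 CPM at 1 mM, a log2 fold change of 4.36 ± 0.80, with each 5 µM library above each 1 mM library (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.03118). No single gene was called: edgeR's quasi-likelihood test gave 0 genes with a smallest Benjamini-Hochberg adjusted p of 0.2123, 106 genes had an unadjusted p under 0.05, against 135 expected by chance, and DESeq2 called 8. All 8 DESeq2 genes were on contig 7, between 128922 and 136719. On data simulated for this comparison, 58 of 100 genes changed 2-fold and 90 of 100 changed 4-fold were recovered. No simulated library lay apart from its group, so this does not show that a 4-fold change would have been called here. EDD73_RS05525 of the contig 7 cluster, for example, stood at 36.24 CPM at 5 µM and 1.412 CPM at 1 mM thiosulfate and was not called.

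The call was lost under several alternatives. With the replicate block its adjusted p was 0.1576 and with only the libraries compared 0.486, the highest of a range from 0.0008467. It was also lost without 5 µM thiosulfate B or C (log2 fold changes 4.38 and 3.55, adjusted p 0.0742 and 0.140) and without 1 mM thiosulfate A, B or C (4.47, 4.07 and 4.6, adjusted p 0.133, 0.275 and 0.181), by edgeR's test. Without 5 µM thiosulfate A, 6 genes were called. Within the first run, with 5 µM thiosulfate C alone against 3 libraries, the cluster differed by 5.26. That value rests on 1 library of 5 µM thiosulfate, whose mean r to its own group was 0.955, beside 0.958 for B.

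Whether the concentration effect itself differed between the sources was tested as an interaction. The contig 15 clusters, lower at 5 µM than at 1 mM for sulfate, stood at 869.9 ± 382.8 and 902.1 ± 301.9 CPM (59156 to 62347) and at 1421 ± 715.3 and 1543 ± 513 CPM (62507 to 66171) in 5 µM and 1 mM thiosulfate. Their interactions were 2.40 ± 0.52 and 2.70 ± 0.60 on the log2 scale, and that of the contig 8 cluster was 1.31 ± 0.29 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.03035 for each). With the replicate block these 3 clusters missed the threshold, each at an adjusted p of 0.05195. The interaction of the contig 7 cluster at 130956 to 136719, 2.95, missed the threshold (edgeR, adjusted p = 0.117). Without 5 µM thiosulfate C it was 2.14 (edgeR, adjusted p = 0.262), and over its alternatives it ran from 1.85 to 4.13. For EDD73_RS00690 the interaction was -3.29 ± 0.67 (edgeR, adjusted p = 0.04207). It missed the threshold under 14 of 20 alternatives, among them the replicate block (-3.10, edgeR, adjusted p = 0.05178), with an adjusted p of 8.627e-06 to 0.255 over all of them. In all, 18 genes, 16 higher and 2 lower, and 9 clusters were called. Calls went to 8 genes and 0 clusters with the replicate block and to 2 genes and 0 clusters with a sequencing run term. With no filter on low counts, and with only the libraries compared, edgeR called 0 genes.

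These counts depended on single libraries. Without 5 µM sulfate B, 442 genes and 59 clusters were called, and without 5 µM thiosulfate B 52 genes and 24 clusters. Leaving out 5 µM thiosulfate C gave 5 genes and 0 clusters, and leaving out 1 mM thiosulfate B gave 12 genes and 5 clusters. Calls were 0 for genes and clusters without 5 µM sulfate A or C, 1 mM sulfate A, B or C, 5 µM thiosulfate A, or 1 mM thiosulfate A or C, by edgeR's test; with all libraries 532 genes had an unadjusted p under 0.05 and DESeq2 called 144. Without 5 µM sulfate B and 5 µM thiosulfate C together, edgeR called 520 genes and 74 clusters.

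Across the 2708 genes, which are not independent replicates, log2 fold changes of 5 µM against 1 mM correlated between sulfate and thiosulfate at r = 0.28 (rho = 0.28), with no library in common; r was 0.17 without 5 µM thiosulfate B and 0.17 without 1 mM thiosulfate B. Of the 649 genes called for sulfate, 480 (74.0%) had the same sign for thiosulfate. For methionine against thiosulfate at 1 mM, which is not a comparison of concentrations, 496 (76.4%) had the same sign. There r was 0.1 and rho 0.26 over all genes, with a slope of 0.11. Over the 649 genes, r was 0.48 for the thiosulfate concentrations and 0.31 for methionine against thiosulfate. The median size of the 649 was 1.03 for the sulfate concentrations and 0.18 for the thiosulfate concentrations, with a slope of 0.13. For methionine against thiosulfate it was 0.25. These genes were picked by the sulfate test, which favours large sulfate values, so part of this gap comes from the choice. Over all 2708 genes the medians were 0.44 for the sulfate and 0.17 for the thiosulfate concentrations. No gene was called for both concentration responses, and an overlap test had nothing to count, since edgeR called 0 genes for thiosulfate.

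**Figure D2:**
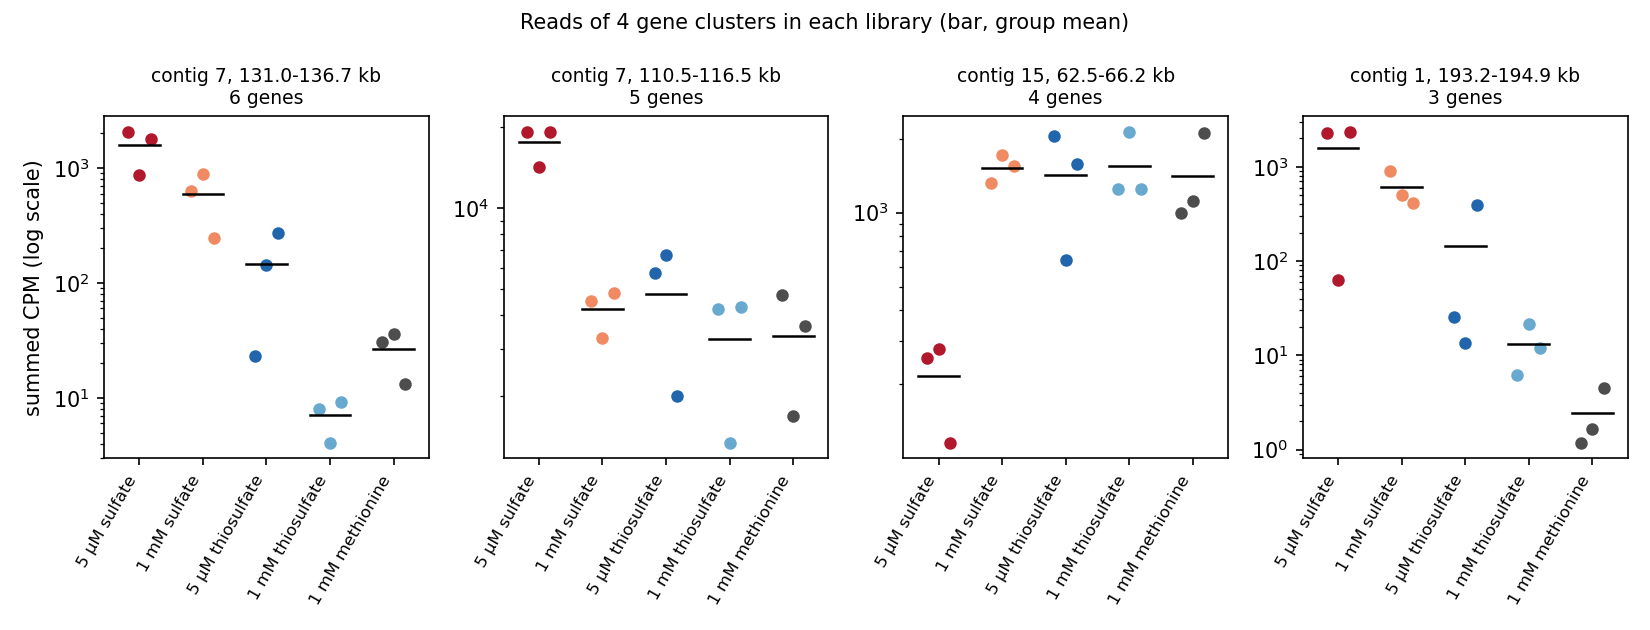
Summed CPM of 4 gene clusters in each library on log axes (points, replicates A, B and C from left to right; bar, group mean of 3). The contig 7 cluster at 131.0 kb ranges from a mean of 1575 CPM in 5 µM sulfate to 7.082 CPM in 1 mM thiosulfate, and the contig 15 cluster is lowest in 5 µM sulfate, at 216.7 CPM.

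At 1 mM, thiosulfate and sulfate cultures differed in the contig 7 cluster. This 6-gene cluster at 130956 to 136719 stood at 7.082 ± 2.669 CPM with thiosulfate and 590.1 ± 324.7 CPM with sulfate, a log2 fold change of -6.38 ± 0.87 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.001526), lower in all 3 libraries. It was the 1 cluster called, and stayed called under each alternative run, with log2 fold changes from -7.10 to -5.96. Its members EDD73_RS05525 (134749 to 135921) and EDD73_RS05510 (131789 to 132649) were lowest, at -6.67 ± 0.98 and -6.54 ± 1.03 (edgeR, adjusted p = 0.008141 for both). With thiosulfate they stood at 1.412 ± 0.5853 and 0.7357 ± 0.6344 CPM, so the size of these fold changes rests on few reads. In all 12 genes were called, each lower with thiosulfate and by at least 2-fold, and 11 of them lay on contig 7 between 117694 and 136719.

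DESeq2 called 38 genes here, 14 on contig 7. By edgeR's quasi-likelihood test, 0 genes were called without 1 mM thiosulfate A or B and 1 without C, with 240 genes at an unadjusted p under 0.05 in the full set, and without 1 mM sulfate B 8 genes were called. EDD73_RS05525 and EDD73_RS05510 then had log2 fold changes of -6.86 and -6.58 without 1 mM thiosulfate A, -6.34 and -5.96 without B, and -6.86 and -7.49 without C, with Benjamini-Hochberg adjusted p of 0.0639 to 0.0825. Over their alternatives, the adjusted p ran from 8.344e-12 to 0.0765 and from 2.912e-09 to 0.0825 by edgeR's test or DESeq2. Fitted to only the 6 libraries compared, edgeR called 197 genes, 97 higher and 100 lower, and 18 clusters. A sequencing run term gave 13 genes and 2 clusters. Within the first run, with 3 libraries against 1 and the spread taken from the other groups as well, 11 genes and the cluster were called, the cluster at -6.49 ± 0.94 (edgeR, adjusted p = 0.01184).

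**Figure D3:**
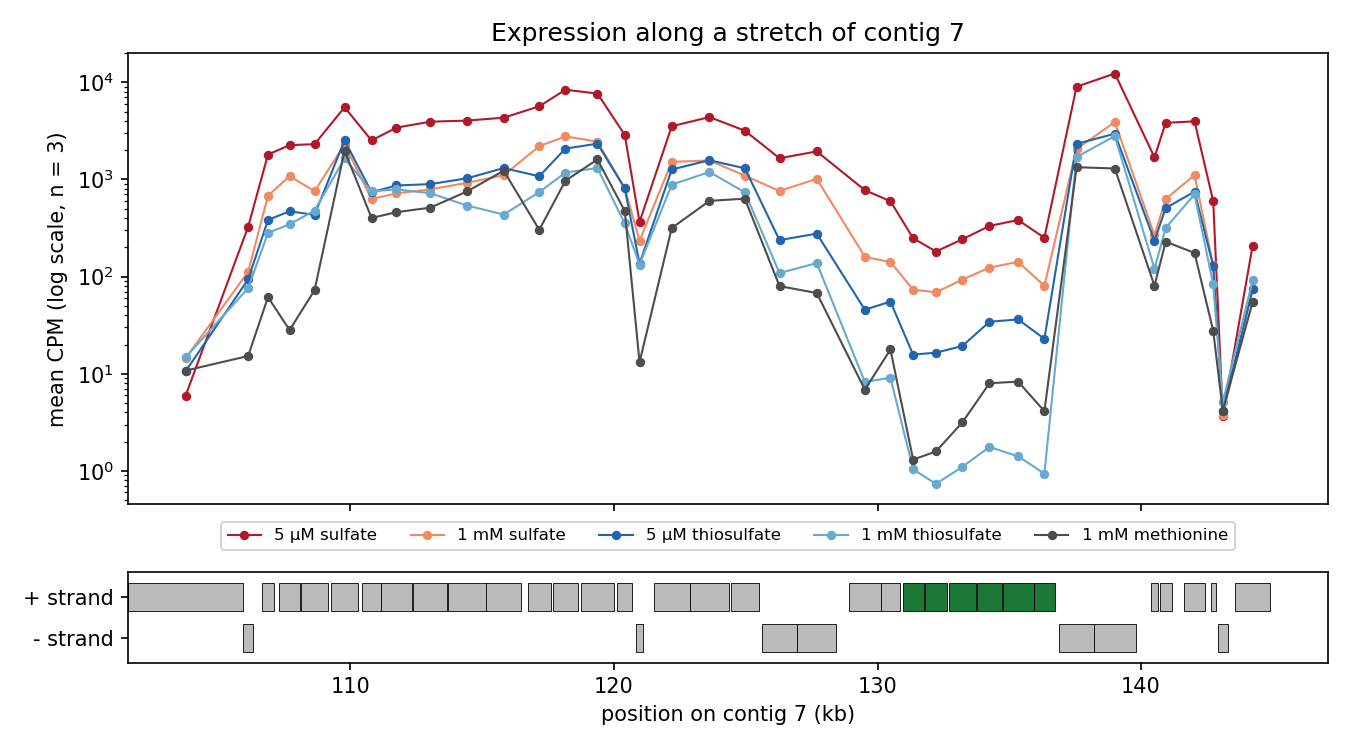
Mean CPM (log axis, n = 3 per group) of 37 genes along contig 7 from 101568 to 144908, with gene positions and strands below and the 6-gene cluster at 130956 to 136719 in green. Across that cluster the line for 5 µM sulfate is highest and that for 1 mM thiosulfate lowest.

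At 5 µM, the contig 7 cluster was again lower with thiosulfate, at 145.3 ± 123.7 CPM against 1575 ± 629.5 CPM with sulfate, a log2 fold change of -3.44 ± 0.75. The contig 19 cluster fell from 4065 ± 1847 to 942.5 ± 172.3 CPM (-2.11 ± 0.32). The contig 15 clusters were higher with thiosulfate, by 2.71 ± 0.45 at 62507 to 66171 and 2.20 ± 0.38 at 59156 to 62347. Each of these 4 clusters separated the 3 libraries of one group from those of the other, and their adjusted p-values were 0.009839, 0.002259, 0.003444 and 0.003758 (edgeR's quasi-likelihood test, Benjamini-Hochberg). Their calls were lost under 3, 1, 1 and 1 of 11 alternatives. Clusters on contig 12 (39636 to 42443), contig 5 (154718 to 157457), contig 2 (157876 to 165995) and contig 7 (110454 to 116475) were less steady. They stood at 1.30, 1.12, -2.27 and -1.87, and their calls were lost under 6, 5, 7 and 6 of 11. Over the stretch of 37 genes on contig 7 from 101568 to 144908, chosen after its values were seen, 31 genes were lower with thiosulfate at 5 µM. Of these 37 genes, 21 were higher and 1 lower in the comparison of 5 µM with 1 mM sulfate.

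EDD73_RS09150 and EDD73_RS09155 (64160 to 65347), both of the contig 15 cluster, rose by 2.96 ± 0.55 and 2.76 ± 0.45 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.007608 and 0.004745). EDD73_RS05495 on contig 7 (128922 to 130118) had a log2 fold change of -4.08 ± 0.74 and EDD73_RS00690 one of -4.07 ± 0.52 (edgeR, adjusted p = 0.007406 and 0.002429). Without 5 µM thiosulfate C, EDD73_RS05495 stood at -5.21 and the contig 7 cluster at -4.25, both still called. The cluster was lost without 5 µM sulfate A, at -3.19 (edgeR, adjusted p = 0.0552), and with a sequencing run term, at -2.97 (adjusted p = 0.07188; over its alternatives 0.002689 to 0.1367). Within the first run, with 5 µM thiosulfate C alone against 3 libraries, the cluster stood at -2.50 ± 1.12 and was not called (edgeR, adjusted p = 0.1721). EDD73_RS05495 missed the threshold with the run term as well (edgeR, adjusted p = 0.0518; over its alternatives 1.183e-08 to 0.1526).

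In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 333 genes, 158 higher and 175 lower with thiosulfate at 5 µM, and 56 clusters, 33 higher and 23 lower. Single libraries moved these counts. Without 5 µM sulfate B, 929 genes and 119 clusters were called, and without that library and 5 µM thiosulfate C 1083 genes and 147 clusters, including 314 of the 333 genes. Genes called fell to 50, 53, 111 and 205 without 5 µM sulfate A, 5 µM sulfate C, 5 µM thiosulfate A and 5 µM thiosulfate C, and clusters to 6, 13 and 22 without 5 µM sulfate A, 5 µM sulfate C and 5 µM thiosulfate A. In a fit to only the 6 libraries compared edgeR called 0 genes and 0 clusters, against 795 genes with an unadjusted p under 0.05 in the full fit and 523 by DESeq2. With a sequencing run term 30 genes, all among the 333, and 12 clusters were called. Within the first run 5 µM thiosulfate C was the only library of its arm, so no count is given there.

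Methionine was compared with sulfate at 1 mM as an organic against an oxidised source. A cluster of 3 genes on contig 1 (193157 to 194927) was lowest with methionine, at 2.448 ± 1.793 CPM against 603.7 ± 260.9 CPM with sulfate, a log2 fold change of -7.91 ± 1.59. The contig 7 cluster stood at 26.57 ± 11.89 CPM against 590.1 ± 324.7 (-4.48 ± 0.79), and the contig 19 cluster fell from 1170 ± 253.6 to 396.1 ± 109.6 CPM (-1.56 ± 0.32). The contig 2 cluster at 942 to 5088 rose to 146.3 ± 44.79 from 43.63 ± 8.443 CPM (1.74 ± 0.39). Each of these 4 separated the groups in all 6 libraries, with adjusted p-values of 0.008314, 0.00617, 0.008314 and 0.01291 (edgeR's quasi-likelihood test, Benjamini-Hochberg). On the contig 7 stretch, 20 of the 37 genes were lower with methionine and 0 higher by edgeR's test.

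EDD73_RS15245 on contig 11 (39677 to 40600) rose to 132.7 ± 45.96 CPM from 23.01 ± 4.314, by 2.53 ± 0.40, and EDD73_RS05305 on contig 7 (77473 to 79029) by 2.54 ± 0.54 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.006572 and 0.02132). EDD73_RS00910 (194304 to 194927) and EDD73_RS00905 (193396 to 194307), both of the contig 1 cluster, stood at -8.68 ± 1.94 and -7.71 ± 1.43 (edgeR, adjusted p = 0.0263 and 0.01535). EDD73_RS00910 missed the threshold when any 1 of the 6 libraries was left out, at -8.32, -8.77 and -8.86 without 1 mM sulfate A, B and C and -8.23, -8.41 and -9.87 without methionine A, B and C (edgeR, adjusted p 0.0505 to 0.102; over its alternatives 1.937e-07 to 0.1082). EDD73_RS00905 missed it without methionine B (-7.62) and C (-8.01), and EDD73_RS05305 without 1 mM sulfate A (2.35), B (2.77) and C (2.57) and methionine B (2.71) and C (2.37).

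Several cluster calls were lost as well. The contig 1 cluster (-7.70) and the contig 19 cluster (-1.41) missed the threshold without methionine B, both at an adjusted p of 0.0514 (edgeR's quasi-likelihood test, Benjamini-Hochberg; over their alternatives 0.0003993 to 0.05138 and 0.003736 to 0.05138). Without methionine C the contig 1 cluster was called at -8.74. The contig 2 cluster was lost without 1 mM sulfate A (1.72), 1 mM sulfate C (1.62) and methionine B (1.5), with an adjusted p of 0.005425 to 0.0893 over its alternatives.

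In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 137 genes between methionine and 1 mM sulfate, 44 higher and 93 lower, and 33 clusters, 8 higher and 25 lower. Genes called fell to 18, 18 and 30 without 1 mM sulfate A, B and C, and to 68, 14 and 30 without methionine A, B and C. Clusters fell to 11, 19 and 8 without 1 mM sulfate A, B and C and to 10 without methionine B. DESeq2 called 325 genes, and a fit to only the 6 libraries compared called 463 genes and 77 clusters. With a sequencing run term 8 genes and 9 clusters were called, with EDD73_RS15245, the contig 1 cluster, the contig 7 cluster and the contig 19 cluster among them; EDD73_RS05305, EDD73_RS00910, EDD73_RS00905 and the contig 2 cluster were lost. Within the second run, with 2 libraries against 2, 13 genes and 18 clusters were called, and the contig 7 cluster stood at -4.53 ± 0.96 (edgeR, adjusted p = 0.03885).

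Between methionine and thiosulfate at 1 mM, the contig 7 cluster was low in both, at 26.57 ± 11.89 and 7.082 ± 2.669 CPM, and the difference of 1.91 ± 0.74 missed the threshold (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.3442). The contig 15 cluster at 62507 to 66171 stood at 1406 ± 609.1 and 1543 ± 513 CPM. No gene or cluster was called: edgeR gave 0 genes, with a smallest adjusted p of 0.08888, 242 genes had an unadjusted p under 0.05, against 135 expected by chance, and DESeq2 called 16. For clusters edgeR gave 0, with a smallest adjusted p of 0.1238 and 33 at an unadjusted p under 0.05. Simulated data for this comparison gave back 55 of 100 genes changed 2-fold and 95 of 100 changed 4-fold. Both sets changed at once and independently there, so recovery in the real data may be lower. With the replicate block, and without methionine C, 1 gene was called, and without methionine C 1 cluster. No sequencing run held libraries of both groups, so no value within a run could be had; with a run term 0 genes were called by edgeR.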

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

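The gene-level interaction test, the drawn exchanges of source labels and the tests on the sequencing run term were chosen before their results were seen. The tests on clusters and the other tests in this part were chosen after the result was seen.

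The concentration effect differed between thiosulfate and sulfate by a test of the difference itself, for 18 genes and 9 clusters (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The contig 15 clusters had interactions of 2.70 (62507 to 66171) and 2.40 (59156 to 62347) on the log2 scale, and the contig 8 cluster (41194 to 45852) 1.31. A cluster of 5 genes on contig 4 (91248 to 95848) had 1.06 and a cluster of 3 genes on contig 10 (77392 to 83716) -1.40, both at an adjusted p of 0.04366 (over their alternatives 0.01344 to 0.1481 and 0.03294 to 0.1481), and these calls were lost under 12 of 17 and 13 of 17 alternatives. With the replicate block 0 clusters were called, as without 5 µM sulfate A or C, 1 mM sulfate A, B or C, 5 µM thiosulfate A or C, or 1 mM thiosulfate A or C (edgeR; 70 clusters had an unadjusted p under 0.05 with all libraries and no block). The interaction of EDD73_RS00690 was -3.29, and its call was lost under 14 of 20 alternatives. When the sources were exchanged between libraries of the same concentration, 4 of the 100 splits drawn, the real one included, called at least 18 genes, and 7 of 100 called at least 9 clusters. The highest of the others called 208 genes and 22 clusters. That split put 5 µM sulfate A and C with 5 µM thiosulfate C, which points to a structure of the samples. Of all 32 splits that part every same-letter pair, as the real one does, 2 called at least 18 genes and 2 at least 9 clusters. The other of these (98 genes and 12 clusters, by edgeR) exchanged all 3 libraries of each source at 5 µM alone, which gives the main effect of the source and is not a grouping by chance. Without it, 1 of 31 reached 18 genes and 1 of 31 reached 9 clusters, and the highest others called 16 genes and 6 clusters. With the replicate block the interaction called 8 genes, 5 of them among the 18, and 2 of these 31 splits called at least as many, the highest other 16. The share was thus under 0.05 for genes without the block and not with it, and for clusters it was over 0.05 in the drawn splits, so chance was not excluded for either.

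Library B of 5 µM sulfate differed from A and C of its group in 630 genes, and library C of 5 µM thiosulfate from A and B of its group in 218. These counts took both libraries out of their groups; with 1 library taken out at a time, 439 genes differed for 5 µM sulfate B and 0 for 5 µM thiosulfate C, as for B of that group. Sequencing run was argued against for 5 µM thiosulfate C, since the run difference within 5 µM thiosulfate and that within 1 mM sulfate correlated across genes at r = -0.15. With all libraries thinned to the same depth, the mean r to the own group was 0.937 for 5 µM sulfate B, which argues against depth, and 0.953 for 5 µM thiosulfate C, which decided nothing beside the 0.956 of 5 µM thiosulfate B, the lowest of the other 13 libraries. An exchange of the labels of both libraries stays open. In the column headers, 5 µM sulfate B has the sample number 192 and 5 µM thiosulfate C has 189, each the number that column order gives the other. A first test, the position of 5 µM thiosulfate C between both 5 µM groups (0.39, range 0.28 to 0.53), decided nothing and was replaced after that was seen. In the second, 776 genes differed between this single library and 5 µM sulfate A and C, which decided nothing either, since 5 µM sulfate B as labelled differed from them in 630. Exchanging both libraries called 668 genes between the 5 µM sources, where the labels as given called 333. Both were picked for lying apart from their groups. For 5 µM thiosulfate C this was hardly clearer than for B of that group, with a mean r to the group of 0.955 and 0.958. Regrouping 5 µM sulfate B and 5 µM thiosulfate C by likeness narrows the spread within groups, so this count decides nothing about the labels. Summed over the 12 genes called between the 1 mM sources, the values ran the way of the labels: 3239 CPM in 5 µM thiosulfate C beside 2607 and 2972 in A and B of its group, and 8878 CPM in 5 µM sulfate B, between these and the 17980 and 18490 in 5 µM sulfate A and C. It was not decided either whether B was a 5 µM thiosulfate culture. Of these 12 genes, 11 lay in B above all 3 libraries labelled 5 µM thiosulfate, but 11 of the 12 are on 1 stretch of contig 7 and only 2 were called against 5 µM thiosulfate A and B, where 4 genes were called in all. It stays open as well that 5 µM thiosulfate C was a 1 mM sulfate culture, since 0 genes were called between it and 1 mM sulfate (edgeR), although its 3239 CPM on these 12 genes lay below the 6505, 6408 and 4091 of 1 mM sulfate A, B and C, and a difference between cultures of a group was not tested.

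With a sequencing run term, calls fell from 333 to 30 genes between the 5 µM sources and from 137 to 8 between methionine and 1 mM sulfate. The median ratio of fold changes with the term to those without was 1.02 (quartiles 0.92 to 1.11) for the former and 0.96 (0.89 to 1.04) for the latter. Between the first 2 runs the term rests on 1 mM sulfate and 5 µM thiosulfate alone, each with 1 library in the first run. Run differences in these groups correlated across genes at r = -0.15, so ratios near 1 do not exclude a run effect behind the fold changes. Wider errors where run and group overlap may account for the lost calls between the 5 µM sources, where standard errors grew by a median factor of 1.25 (quartiles 1.2 to 1.3). For methionine the factor was 1.19 (1.13 to 1.23), which left this explanation undecided. No biological explanation was tested for this pattern, which concerns the fits.

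The contig 7 cluster at 130956 to 136719 was high with sulfate and low with 1 mM thiosulfate and with methionine. Sequencing run as the whole cause was argued against by a log2 difference of 7.75 ± 0.52 between 5 µM sulfate and 1 mM thiosulfate, whose 6 libraries all came from the first run. Without 5 µM sulfate B and 5 µM thiosulfate C, the fold change between the 5 µM sources was -4.54 ± 0.89. The 1 mM groups hold neither library. On the 12 genes called between the 1 mM sources, each lay nearer the other 5 µM group than the rest of its own group did. Leaving them out therefore widens the difference and does not test the pattern. As a hypothesis, these genes may answer to the kind of sulfur source, on which the comparison of thiosulfate with sulfate at 1 mM bears, with a log2 fold change of -6.38 (edgeR, adjusted p = 0.001526) and the call kept under all 10 alternatives run. An effect of the amount stays open. Between 5 µM and 1 mM sulfate the cluster was not called (1.42, edgeR, adjusted p = 0.1544), and stood at 0.70 with a sequencing run term. No gene of the cluster was called there. EDD73_RS05495 and EDD73_RS05500, which precede it on the same strand and were chosen after their values were seen, were called higher at 5 µM. They stood at 775.8 and 597 CPM at 5 µM sulfate and 160.2 and 140.8 CPM at 1 mM. The interaction of the cluster was not called either (2.95, edgeR, adjusted p = 0.117), and was 2.14 without 5 µM thiosulfate C. Its call between 5 µM and 1 mM thiosulfate (4.36) was lost under 7 of 10 alternatives. These tests used the data in which the pattern was seen, and unequal growth or sampling time between cultures was not tested.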

How the results depend on the processing

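No named gene or cluster changed direction under any alternative run: of 205 values for named genes 158 stayed on the same side of the threshold and 47 did not, and of 390 for named clusters 260 did and 130 did not. The kept directions were largely fixed by the choice, and they are no evidence of robustness. Named genes had to separate the groups, and clusters were named for being the highest or lowest called. The cluster alternatives, the sequencing run term and the fit without a pair of libraries were chosen after seeing the data. Tests of gene lists and fits without ribosomal and transfer RNA genes were not run, because the file pairs no names with identifiers. Causes were not tested except where stated; a left-out library leaves fewer samples, and where a group keeps 2 the fit still pools the spread over all groups.

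A 2-fold limit, fewer genes by construction, left 345 genes for 5 µM against 1 mM sulfate, 182 for 5 µM thiosulfate against 5 µM sulfate and 87 for methionine against 1 mM sulfate. DESeq2 called 8 genes for 5 µM against 1 mM thiosulfate, 38 for thiosulfate against sulfate at 1 mM, 523 at 5 µM, 325 for methionine against 1 mM sulfate, 16 for methionine against 1 mM thiosulfate and 144 for the interaction. Fitting only the libraries compared gave, for genes and clusters by edgeR, 197 and 18 for the 1 mM sources and 0 and 0 for the 5 µM sources. For methionine against sulfate this fit gave 463 and 77. It gave 0 clusters for the thiosulfate concentrations and 0 genes for the interaction. Between the sources, the full fit gave 12 genes at 1 mM and 333 at 5 µM, the opposite order. These counts therefore do not show at which concentration more genes differed. How far unequal spread caused the switch was not tested. With no filter on low counts the interaction called 0 genes.

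The replicate block gave 0 clusters for the thiosulfate concentrations, 1 gene for methionine against thiosulfate, and 8 genes and 0 clusters for the interaction; besides the calls behind these counts it ended that of a cluster on contig 5 (91148 to 92754) for the sulfate concentrations, at an adjusted p of 0.1044 by edgeR, and it changed no other call of a named gene or cluster. The run term gave 2 clusters for the 1 mM sources, 30 genes and 12 clusters for the 5 µM sources, 8 genes and 9 clusters for methionine against sulfate, and 2 genes and 0 clusters for the interaction. Gaps of 200 bp gave 0 clusters for the thiosulfate concentrations, 2 for the 1 mM sources and 18 for methionine against sulfate, and gaps of 50 bp gave 11 for the last and 0 for the interaction. Without 5 µM sulfate B and 5 µM thiosulfate C, 1083 genes and 147 clusters were called for the 5 µM sources and 520 and 74 for the interaction. RLE size factors and removal of the 10 genes with most reads kept each count within 1.5 times.

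Leaving out 1 library at a time gave 274 to 979 genes and 56 to 122 clusters for the sulfate concentrations, and 0 to 6 genes and 0 to 1 clusters for the thiosulfate concentrations. For the 1 mM sources it gave 0 to 11 genes and 1 cluster throughout, and for the 5 µM sources 50 to 929 genes and 6 to 119 clusters. Methionine against sulfate gave 14 to 68 genes and 8 to 23 clusters, methionine against thiosulfate 0 to 1 of each, and the interaction 0 to 442 genes and 0 to 59 clusters. The correlation of both concentration responses moved from 0.28 to 0.17 without 5 µM thiosulfate B and to 0.17 without 1 mM thiosulfate B. Depth limits the lowest genes. The contig 1 cluster at 2.448 CPM with methionine rests on few reads per library. So do EDD73_RS05525 and EDD73_RS05510 of the contig 7 cluster, at 1.412 and 0.7357 CPM in 1 mM thiosulfate.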

Other observations

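Tests of whether called genes lie together on the contigs were planned before their result was seen, as were the splits of the libraries. The DESeq2 genes between methionine and thiosulfate were looked at after that comparison was seen to give no edgeR calls.

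Between methionine and thiosulfate at 1 mM, the 16 genes that DESeq2 called formed 2 main groups. On contig 6, 5 genes between 60500 and 64852 were higher with methionine, by 1.38 to 1.69 on the log2 scale. On contig 7, 6 genes between 106630 and 124373 were lower with methionine, by -3.61 to -0.98, beside the 6-gene cluster at 130956 to 136719 and not in it. The others were 1 gene on contig 1 (124204 to 125154, -2.17) and 1 on contig 2 (132221 to 133378, -1.87), both lower, and 1 on contig 13 (0.53) and 2 on contig 18 (0.73 and 0.75), higher. None of them passed edgeR's quasi-likelihood test, whose smallest Benjamini-Hochberg adjusted p was 0.08888.

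Whether called genes of neighbouring clusters lie together was tested by shuffling whole clusters along the genome 10000 times. The value taken was the highest number of called genes in 20 neighbouring genes. Clusters are only a guess at transcription units. On contig 7, for example, EDD73_RS05500 ends at 130838, and the cluster at 130956 to 136719 follows on the same strand. A transcript may span such a gap, so the test cannot show change beyond shared transcription units. Between the 5 µM sources, 19 of 20 genes on contig 7 from 108137 to 131747 were called, each lower with thiosulfate, against a median of 11 and at most 18 in the shuffles (permutation p = 1e-04, adjusted over 3 comparisons 0.00015). Between methionine and 1 mM sulfate, 16 of 20 genes on contig 7 from 116729 to 139793 were called, each lower with methionine, against a median of 7 and at most 14 (permutation p = 1e-04, adjusted 0.00015); 1e-04 is the smallest p that these shuffles can give. For 5 µM against 1 mM sulfate the test decided nothing: 20 of 20 genes were called on contig 8 from 29994 to 49687, the highest count possible, and the shuffles reached it with a median of 20 and a permutation p of 0.83.

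With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. The highest other split called 0 genes against 649 for the sulfate concentrations, 1 against 0 for the thiosulfate concentrations, and 0 against 12 for the 1 mM sources. It called 668 against 333 for the 5 µM sources, 0 against 137 for methionine and 1 mM sulfate, and 0 against 0 for methionine and thiosulfate, by edgeR. In clusters the values were 0 against 91, 1 against 1, 0 against 1, 86 against 56, 0 against 33 and 0 against 0. Counting the real split, as many calls came from 1, 10, 1, 2, 1 and 10 of the 10 splits for genes, and from 1, 2, 1, 2, 1 and 10 for clusters. The split with 668 genes put 5 µM sulfate A and C with 5 µM thiosulfate C, the structure described for these libraries, and does not part all same-letter pairs; of those that do, the highest other called 0 genes, for each comparison, and 0 clusters except 1 for the thiosulfate concentrations.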
